A study of Mus musculus with 2 samples.

How the data were processed

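RNA from cultured bone marrow mesenchymal stem/progenitor cells was sequenced on a HiSeq2000, per the labels, in 2 libraries, 1 from PPARg-floxed and 1 from PPARg-deficient cells. The genotype label of each library gave its group. The deposited files hold FPKM per transcript inside an attribute field with other text, as Cufflinks writes it, with lower and upper confidence bounds and read coverage. Other processing is known only in part: TopHat2 2.0.5, Cufflinks 2.0.2, Cuffdiff 2.0.2 and the build mm9 are named, per the submitters' processing notes, without their role or order. The annotation, the filters and the handling of strand are not given in the sources used here. FPKM is relative to each library's own total, so a few abundant genes can shift all others.

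Both deposited files list the same 45543 transcripts in 25707 loci under assembly IDs, without gene symbols, and no mm9 annotation was used here. Gene names were therefore inferred here from transcript structure. A transcript was matched to the GENCODE mouse M21 annotation, which is on a later build, by the ordered lengths of its introns and internal exons on the same chromosome and strand. No coordinate was converted, and all coordinates given are those of the files. A match of the whole chain of at least 2 introns to 1 gene named 17695 loci, a run of 3 lengths found in 1 gene named 346, and a single intron with a terminal exon named 951. In all, 18992 loci received 18947 symbols. Matched against the wrong chromosomes as a check, 0 of 36924 whole chains and 1 of 2883 single introns found a gene. Of 5144 loci with at least 2 whole-chain matches, 5008 pointed to 1 gene, and 124 loci matched several genes. Genes without introns could not be named in this way. Other list members, among them Egr1, Sp7, Hmgcs1 and Ifit3, found no match for a cause that was not examined, and unmatched members are left out of their lists.

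FPKM was summed over the transcripts of a gene. Loci with at least 1 FPKM in at least 1 library and a longest transcript of at least 300 nt were kept, which left 10745 loci, 8626 of them named. Of the 2119 unnamed loci, 1498 had a single exon. The fold was computed as log2 of FPKM plus a pseudocount of 1, deficient over floxed, which understates changes of low genes. A locus was called by size alone, at 2-fold. With 1 library per group no test, standard error or p-value was computed, and leaving out a replicate was not possible. Some abundant loci are listed at 0 in 1 library only, so a 0 can be a failed estimate, and no fold is given for such a gene. It stays in the counts, where 18 kept loci at 0 in the floxed library had at least 5 FPKM in the deficient library and 15 the reverse.

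The genes to name were set by a rule fixed before the data were examined. It takes Pparg, then the 12 highest and 12 lowest genes of at least 5 FPKM, at least 2-fold and with deposited bounds of the major transcript that did not overlap, leaving out predicted genes, RIKEN clones, small RNAs, pseudogenes and unnamed loci. It also takes from each of 35 fixed lists up to 4 kept members of at least 5 FPKM with the largest fold, and, from marker lists of other cell types and the sex-linked list, up to 4 members under that level with the highest FPKM. A few genes outside the rule, such as Ptprc, Pecam1, Cd3e, Xist and Rspo2, were named after their values were seen. For brevity the text gives values for only some of the list members that the rule takes, picked after their values were seen, and the others are not reported here. The median of each list with at least 5 kept members was placed among 10000 random lists of the same size, matched in 10 bins of mean expression.

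The steps were tested on simulated data for this comparison over 9350 kept genes, with an assumed noise of 0.2 (SD, log2 scale) per library, since no spread between cultures could be measured. The simulated genes varied independently, with no shift common to all genes. The rates found hold for that setting only and give no rate of false calls, of genes or of lists, in these libraries. At 4-, 8- and 16-fold all 50 changed genes per size were called, at 2-fold 27 of 50, and 2 of 9150 unchanged genes. Of 200 unchanged lists of 20 genes, 11 fell outside the central 95%, and all 200 lists shifted by 0.5 on the log2 scale were found. Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a filter of 5 FPKM, TPM, upper-quartile scaling, centring on the median gene, the most abundant transcript, all transcript lengths, non-overlapping bounds, and folds of 1.5 and 4. Chosen after seeing the data were TPM over all transcripts, a pair of scalings that leave out the 100 most abundant genes of each library, named genes only, and removal of GC, length and expression trends by running medians over 501 genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.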

Results

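Gene expression was measured by RNA sequencing in mesenchymal stem/progenitor cells from the bone marrow of 3-month-old CD-1 mice, grown in DMEM with fetal bovine serum. These stromal cells can form fat cells and bone-forming cells. PPARg, encoded by Pparg, is a nuclear receptor and the main transcription factor of fat cell formation. There were 2 libraries, 1 from PPARg-floxed cells and 1 from PPARg-deficient cells, so the single comparison was of deficient against floxed cells, and none of its differences has a replicate check. Transcript coverage summed to 1383 megabases in the floxed library and 1728 megabases in the deficient library, and 8278 and 10284 genes reached 1 FPKM (fragments mapped to a transcript, scaled by its length and by the library total). Read counts were not given, so the number of fragments behind a value is unknown, and the deposited bounds of a transcript's FPKM describe the estimate within 1 library.

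Pparg lay on chromosome 6 from 115310824 to 115440419 (mm9), with 6 transcripts of up to 8 exons. It fell from 6.86 FPKM in the floxed library to 1.39 FPKM in the deficient library, a log2 fold of -1.72 with a pseudocount of 1 FPKM. The transcript that starts at 115312376 held 4.69 FPKM in the floxed library (deposited bounds 3.38 to 6.0), and in the deficient library its upper bound was 0.14 FPKM. The transcript that starts at 115311239 was at 2.17 FPKM (1.21 to 3.13) and 0.96 FPKM (0.38 to 1.53), bounds that overlap. The transcript that starts at 115311099 went the other way, from about 0 (upper bound 0.14) to 0.43 FPKM (0 to 0.89). The labels do not say which exons were floxed, and exon lines in the files repeat the transcript value, so signal over a deleted part could not be separated from signal over the rest of Pparg.

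**Figure D1:**
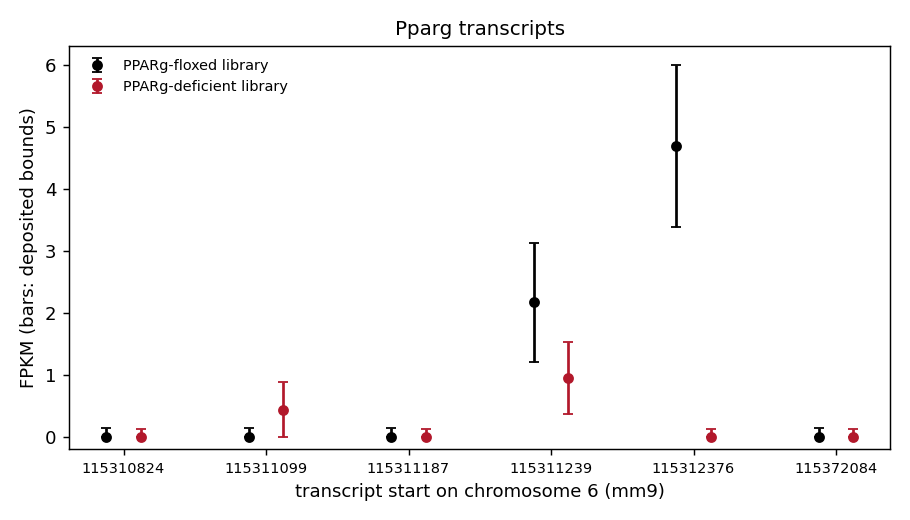
FPKM of the 6 Pparg transcripts (y axis) by the start of each transcript on chromosome 6 in mm9 (x axis), for the floxed library (black) and the deficient library (red), with bars for the deposited bounds. The transcript that starts at 115312376 held 4.69 FPKM in the floxed library and had an upper bound of 0.14 FPKM in the deficient library.

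The comparison asked which genes are expressed differently when PPARg is lost. Most interferon response genes, Sfrp2, Spp1, Postn and the fat cell genes Lpl and Adipoq were at least 2-fold lower in the deficient library. Id1, Id2, Crip1 and 26 of 30 cell cycle genes were at least 2-fold higher as deposited. Relative to the median gene, 12 of the 30 were at least 2-fold higher, and 26 lay above it. The median gene was itself higher by 0.86 on the log2 scale (1.81-fold), so log2 folds below are relative to that median gene unless stated otherwise, and FPKM values are as deposited. As deposited, 4510 of 10745 kept loci were at least 2-fold higher and 505 at least 2-fold lower, so 89.9% of the calls were higher. Centred on the median gene, 1107 were higher and 1268 lower, so 46.6% were higher. Upper-quartile scaling gave 1202 higher and 1306 lower. Across genes, which are not independent replicates, log2 values of the libraries had a Pearson r of 0.89 and a Spearman rho of 0.83.

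**Figure D2:**
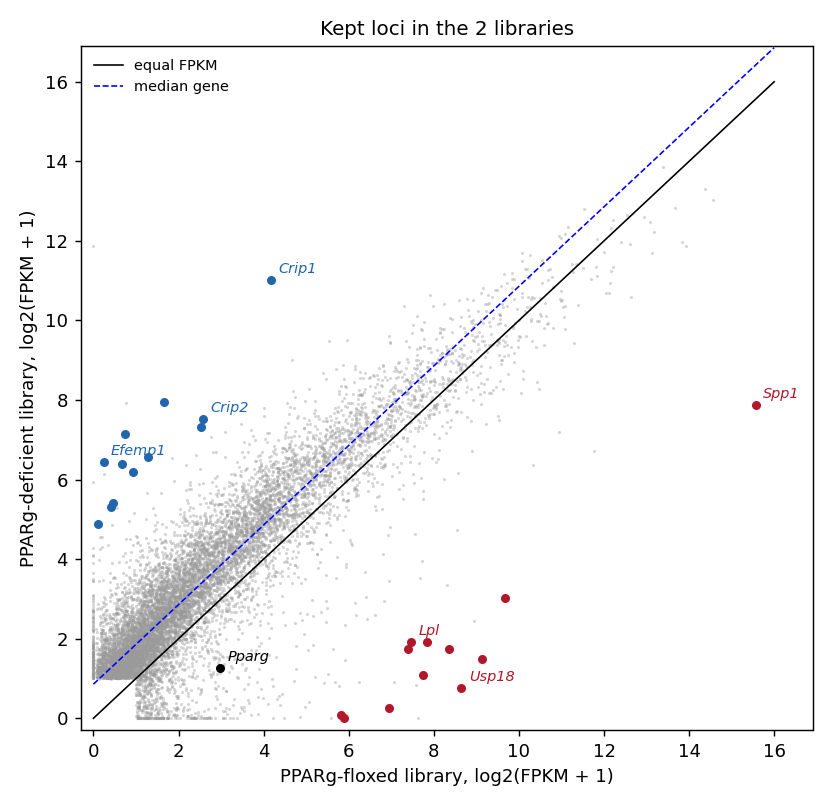
Each point is a kept locus, with log2(FPKM + 1) in the floxed library on the x axis and in the deficient library on the y axis. The solid line marks equal FPKM, the dashed line the median gene (log2 fold 0.86), and colour marks Pparg (black) and the 12 highest (blue) and 12 lowest (red) named genes. Spp1 lies farthest to the right, at 48577 FPKM in the floxed and 234 FPKM in the deficient library.

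Among the 12 lowest genes, Spp1, which encodes the matrix protein osteopontin, fell from 48577 to 234 FPKM, a relative log2 fold of -8.55. Usp18, which encodes a protease that removes ISG15 from proteins, fell from 401 to 0.68 FPKM (-8.76). Isg15 itself fell from 122 to 0.19 FPKM (-7.54), and Ifit1 from 329 to 2.35 FPKM (-7.48). Oasl2 was at 58.0 FPKM in the floxed library and was listed at 0 in the deficient library. Ifi202b fell from 55.4 to 0.07 FPKM (-6.58). Lpl, which encodes lipoprotein lipase, fell from 176 to 2.78 FPKM (-6.41). The other lowest genes were Itm2a (556 to 1.80 FPKM), Ldhb (822 to 7.15), Hp, which encodes haptoglobin (212 to 1.12), Mgst1 (227 to 2.75) and Cthrc1 (168 to 2.34). Ifit1, Oasl2 and Ifi202b belong to multigene families with similar copies, so reads could be split among relatives and their values are uncertain.

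Among the 12 highest genes, Crip1 rose from 17.0 to 2068 FPKM, a relative log2 fold of 5.98, although its major transcript in the floxed library had bounds of 0 to 35.9 FPKM. Its neighbour Crip2 rose from 5.0 to 182 FPKM (4.07). Anxa8, which encodes an annexin, rose from 0.66 to 142 FPKM (5.57), and Crabp1, a retinoic acid binding protein gene, from 2.16 to 244 FPKM (5.42). Aldh1a1, which encodes a retinaldehyde dehydrogenase, rose from 0.34 to 38.6 FPKM (4.03). The matrix protein genes Efemp1 (0.18 to 86.0 FPKM) and Mfap5 (0.60 to 82.5 FPKM) rose as well. The others were Adm, which encodes adrenomedullin (0.37 to 41.6 FPKM), Cox6a2 (1.45 to 93.8), Fhl1 (4.75 to 160), Ankrd1 (0.07 to 28.3) and Serpinb9b (0.90 to 72.2), the last from a multigene family and so uncertain.

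Gene lists fixed before the data were examined were set against 10000 random lists matched on expression, as a description of these libraries. Of 35 lists, 23 had at least 5 kept members. Of these, 6 had medians below the central 95% of random lists and 4 above it, where lists of unrelated genes would give 1.15. Counts of members below use the 2-fold rule relative to the median gene.

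Interferon response genes were the lowest list, with a relative median of -3.29 at percentile 0.00. Of 20 kept members, 19 fell and 0 rose, and as deposited 17 were at least 2-fold lower. Beside Usp18, Isg15 and Ifit1, Gbp3 fell from 30.5 to 0.22 FPKM (-5.55). Genes of the Wnt pathway had a relative median of -2.44 (percentile 0.00), with 6 of 10 members lower and 1 higher (5 and 3 as deposited). Of 26 entries 10 were kept. With no filter on low values the list stayed below the random range, but at -0.37 from its random median, against -2.51 with the filter. The list mixes secreted modulators, agonists among them, with other pathway genes, so its median gives no direction of Wnt signalling. The secreted Wnt modulators Sfrp2 (371 to 25.6 FPKM, -4.67), Sfrp4 (7.26 to 0.14 FPKM, -3.72) and Sfrp1 (10.7 to 0.67 FPKM, -3.67) fell, and Ccn5, a matricellular protein gene, rose from 4.64 to 76.2 FPKM (2.92). Rspo2, which encodes a secreted Wnt agonist, was at 6.404 and 19.5 FPKM (0.61).

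The adipocyte program and PPARg targets had a relative median of -0.95 (percentile 0.03), with 5 of 11 kept members lower and 1 higher. As deposited its median was -0.09, with 3 lower and 2 higher. Of 30 entries 11 were kept and 1 was not matched. The rest, among them Plin1, Lep and Cd36, stayed under 1 FPKM in both libraries. With no filter on low values the list stayed below the random range, at -0.25 from its random median, against -0.99 with the filter. Fabp4 was at 17.6 and 12.7 FPKM (-1.30) and Plin2 at 125 and 117 FPKM (-0.95). Lpl fell, and Adipoq, which encodes the hormone adiponectin, fell from 9.87 to 0.10 FPKM (-4.16). Fabp5, a fatty acid binding protein gene, rose from 15.2 to 220 FPKM (2.92), and Hilpda was at 12.8 and 34.0 FPKM (0.48). Fatty acid oxidation genes had a relative median of -0.43 (percentile 1.20), but 12 of 13 lay within 2-fold of the median gene, and as deposited 1 was higher and 0 lower. Of these genes Acadm was at 72.9 and 47.6 FPKM (-1.46), Acaa2 at 62.7 and 107 FPKM (-0.09), Hadha at 19.7 and 30.9 FPKM (-0.23) and Cpt2 at 2.42 and 6.52 FPKM (0.28). With no filter on low values this list lay at percentile 4.83, inside the random range.

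Osteoblast genes had a relative median of -0.88 (percentile 0.06), with 6 of 14 members lower and 3 higher (5 and 4 as deposited). As deposited the list median was -0.03. Of 27 entries 5 were not matched: Sp7, Bglap, Bglap2, Msx2 and Ifitm5. Col1a1 (173 and 191 FPKM), Col1a2 (205 and 255 FPKM) and Sparc (1432 and 1522 FPKM) differed little as deposited, and Bmp4 rose from 9.32 to 46.9 FPKM (1.36). Spp1, Postn (59.2 to 4.10 FPKM, -4.42) and Alpl, the tissue-nonspecific alkaline phosphatase gene (7.49 to 0.14 FPKM, -3.76), fell, and Col5a2 rose from 11.4 to 57.8 FPKM (1.39). Extracellular matrix genes had a relative median of -0.38 (percentile 1.64), with 9 of 25 lower and 4 higher. As deposited this balance turned, with 8 lower and 9 higher. Thbs2 fell from 1282 to 81.9 FPKM (-4.81) and Tnc from 60.5 to 13.8 FPKM (-2.92), while Lox, which encodes lysyl oxidase, rose from 31.3 to 128 FPKM (1.14). Among genes of at least 5 FPKM the matrix list lay at percentile 34.59.

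The list of TGFb and BMP response genes was the highest, with a relative median of 1.12 (percentile 100) and 8 of 15 members higher against 2 lower (8 and 0 as deposited). Id1 rose from 0.16 to 18.6 FPKM (3.23) and Id2 from 13.0 to 127 FPKM (2.34), genes of transcriptional inhibitors induced by BMP signals. Ccn2 rose from 0.99 to 14.7 FPKM (2.12). Of its members Id1, Ccn2, Ltbp2 and Smad7 were under 1 FPKM in the floxed library and passed the filter through the deficient library alone. With no filter on low values the list lay at percentile 88.30. It mixes ligand genes such as Tgfb2 and Tgfb3 with response genes, so its median gives no direction of TGFb or BMP signalling. Cell cycle genes had a relative median of 0.78 (percentile 100), and of 30 members 12 rose and 0 fell, with 26 at least 2-fold higher as deposited. Ube2c rose from 9.70 to 78.1 FPKM (2.03), Aurkb from 3.65 to 24.4 FPKM (1.59), Cdc20 from 0.49 to 6.83 FPKM (1.54) and Cdk1 from 32.9 to 167 FPKM (1.45).

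Genes of the unfolded protein response had a relative median of 0.63 (percentile 99.59), with 3 of 14 higher and 2 lower (8 and 0 as deposited). Ddit3 rose from 25.1 to 221 FPKM (2.23), Trib3 from 0.30 to 5.18 FPKM (1.39) and Atf4 from 11.97 to 55.9 FPKM (1.28), and Hspa5, the BiP chaperone gene, was at 132 and 427 FPKM (0.83). Immediate early genes had a relative median of 0.89 (percentile 99.35), with 3 of 7 higher and 2 lower (5 and 1 as deposited). Fos rose from 2.10 to 16.2 FPKM (1.61) and Dusp1 from 1.34 to 11.2 FPKM (1.53). The unfolded protein list lay at percentile 94.56 with a pseudocount of 5 FPKM, and the immediate early list at 95.93 with 0.1 FPKM.

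**Figure D3:**
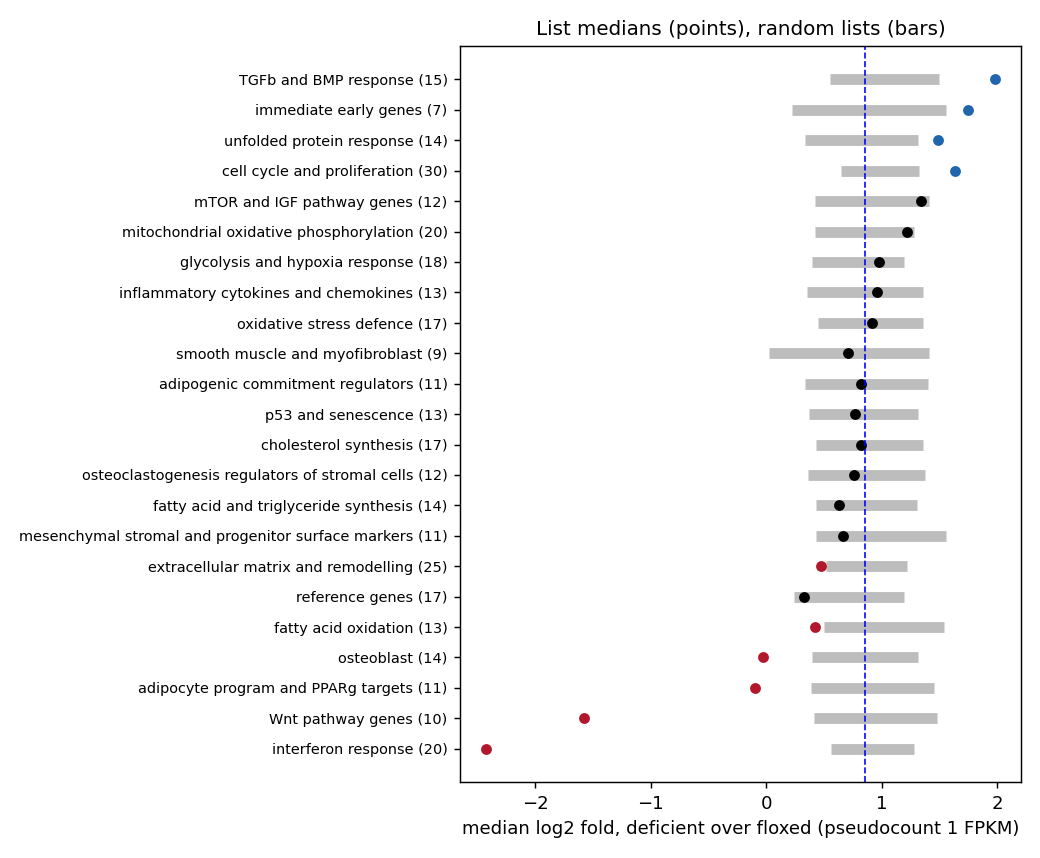
Median log2 fold of each gene list as deposited (points, x axis, with a pseudocount of 1 FPKM) and the central 95% of medians of 10000 random lists matched on expression (grey bars). The number of kept members follows each name, and the dashed line marks the median gene (0.86). Interferon response genes lie farthest below their random range, with a median of -2.43, and TGFb and BMP response genes farthest above, with 1.98.

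The other 13 lists lay inside their random range. Genes of mTOR and IGF signalling were near its upper end (percentile 95.95, relative median 0.49), with Igfbp6 (0.20 to 7.0 FPKM, 1.87) and Eif4ebp1 (14.1 to 88.9 FPKM, 1.71) higher. That list passed above the range in 8 alternatives, at percentile 98.28 with TPM and 99.79 with the most abundant transcript. Nuclear-encoded oxidative phosphorylation genes were at percentile 95.37, where Ndufs3 rose from 1.20 to 16.4 FPKM (2.12) and Uqcrc1 from 8.74 to 58.0 FPKM (1.74). The p53 and senescence list was at percentile 39.09 although 5 of 13 members rose, among them Bax (24.9 to 298 FPKM, 2.68) and Cdkn1a, the p21 gene (3.62 to 44.2 FPKM, 2.43). Among genes of at least 5 FPKM, a level that Cdkn1a, Mdm2, Ccng1 and Perp reached in the deficient library only, that list lay at percentile 100. Reference genes were at percentile 4.66, with a relative median of -0.53 (0.33 as deposited) and 13 of 17 below the median gene. Of them Actb was lower (24060 to 8421 FPKM, -2.37) and B2m lower (6389 to 1549 FPKM, -2.90). The relative medians of fatty acid oxidation (-0.43) and extracellular matrix genes (-0.38), though below their random ranges, lay above that of the reference genes.

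Glycolysis and hypoxia genes were at percentile 79.22, with Adm and Pgam1 (6.44 to 46.8 FPKM, 1.83) higher. Inflammatory cytokine and chemokine genes were at 67.73, with Il1rl1 higher (2.02 to 50.01 FPKM, 3.22) and Cxcl10 lower (6.398 to 0.48 FPKM, -3.18). Oxidative stress genes were at 55.18, with Sod2 higher (2.04 to 28.6 FPKM, 2.43) and Gpx3 lower (15.0 to 0.43 FPKM, -4.34). Smooth muscle and myofibroblast genes were at 47.56, where Actg2 fell from 738 to 181 FPKM (-2.88) and Tpm2 rose from 50.05 to 221 FPKM (1.27). In that list Acta2 was at 2154 and 4656 FPKM (0.25) and Tagln at 292 and 576 FPKM (0.12). Adipogenic commitment regulators were at 43.20, with Klf4 at 2.18 and 10.2 FPKM (0.96). Cholesterol synthesis genes were at 37.45, with Cyp51 at 9.52 and 35.6 FPKM (0.94). Stromal regulators of osteoclast formation were at 34.37, with Cxcl12 higher (60.4 to 318 FPKM, 1.52) and Wnt5a lower (29.1 to 4.57 FPKM, -3.29). Fatty acid and triglyceride synthesis genes were at 14.81, with Me1 at 2.11 and 7.67 FPKM (0.62). Stromal surface markers were at 13.68, with Cd200 higher (0.36 to 28.0 FPKM, 3.56) and Alcam lower (8.80 to 1.98 FPKM, -2.58).

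Most blood and endothelial cell markers were near or at 0 FPKM in both libraries. Ptprc, the pan-leukocyte gene, was listed at 0 in both, as were Pecam1 and Cd3e. Of macrophage markers Lyz2 was at 0.26 and 19.5 FPKM, Lgmn at 25.7 and 75.9 FPKM and Cd14 at 4.52 and 12.5 FPKM. Of osteoclast markers Ctsk was at 44.0 and 150 FPKM and Acp5 at 4.73 and 0.65 FPKM. Among granulocyte markers Camp was at 6.41 and 6.78 FPKM, and the basophil gene Mcpt8 at 21.5 and 4.04 FPKM. Of nerve and Schwann cell markers Pmp22 was at 51.0 and 156 FPKM and S100b at 3.41 and 0.22 FPKM. No lymphocyte, erythroid, megakaryocyte or endothelial marker reached 1 FPKM, with Lck at 0.53 FPKM in the floxed library and Hbb-bs and Flt1 at 0.62 and 0.14 FPKM in the deficient library. Of chondrocyte genes Sox9 was at 4.25 and 2.76 FPKM, and of skeletal muscle genes Mylpf was at 1.11 and 2.52 FPKM. Of antigen presentation genes B2m was at 6389 and 1549 FPKM, H2-D1 at 3.06 and 7.24 FPKM and Tapbp at 5.03 and 3.23 FPKM. Xist was listed at 0 in both libraries, and the Y-linked genes Eif2s3y (24.5 and 69.0 FPKM) and Ddx3y (13.8 and 26.0 FPKM) were present in both.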

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

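The tests of the higher median gene and of white blood cells were chosen only after the result was seen, and the 3 patterns weighed here were picked after all gene and list values had been looked at. The trend removals for the interferon and cell cycle lists were set down before their results were seen, although that alternative was added after the data were examined.

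Signal outside the named genes appeared at the mitochondrial locus, from 17 to 16299 on chromosome M (mm9), which was listed at 0 in the floxed library and at 3723 FPKM in the deficient library. Transcripts under 300 nt held 81.7% of summed FPKM in the deficient library and 61.6% in the floxed library. Their part of the covered bases was smaller: transcripts of at least 300 nt held 81.5% in the deficient and 91.4% in the floxed library. The comparison leaves out loci whose longest transcript is under 300 nt, but short transcripts of kept loci stay in their sums.

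The median kept locus was higher in the deficient library by 0.86 on the log2 scale, but bias by GC content or length as the whole source would leave some of 10 equal bins of genes near 0, and the lowest bin was at 0.74 by GC and at 0.60 by length. More coverage taken by short transcripts in the deficient library would lower the FPKM of longer ones there. The log2 ratio of the coverage share left to longer ones was -0.17, which argues against short transcripts as the source of a higher median. TPM over all transcripts brought the median to 0.003. That scaling divides by summed FPKM, most of it in short transcripts in both libraries, so it cannot decide whether they took coverage. Abundant genes such as Spp1 and Actb taking a larger part of the floxed library may account for some of the shift: scaling without the 100 most abundant genes of each library left 0.4273, just under the bound of 0.4287 (0.5 times the shift) below which this test counts for them. That margin decides nothing, because 3 versions of this scaling were tried: the first, on named genes only, left 0.07, the tested one 0.4273, and a last one, built after that close outcome and keeping the pseudocount in the deposited unit, left 0.34. How much abundant transcripts explain, and whether a global change with the genotype adds to it, stays open.

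Interferon response genes lay far below matched lists. Removing GC, length and expression trends left the list median at -3.51 relative to its random median, which argues against those trends as its source. White blood cells in the floxed culture stay open. The highest of 9 white blood cell genes there, several of them from the macrophage list, was Cd53 at 1.57 FPKM. The interferon genes had a median of 16.5 FPKM. But 6 of the 9 are listed at 0 with no upper bound, and most had been seen before that list of 9 was written. The basophil gene Mcpt8 was at 21.5 FPKM. Of the other genes in its list, though, Kit was at 0.20, Cma1 at 0.25 and the rest listed at 0. With 1 library per genotype, a difference between the cultures other than the genotype, such as exposure to interferon, could give the same pattern and cannot be told apart from loss of PPARg.

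Cell cycle genes lay above matched lists. After removal of GC, length and expression trends the list stood 0.71 above its random median, which argues against those trends. A difference in growth or density between the cultures could act alike, and with 1 library per genotype it cannot be told apart from an effect of PPARg.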

How the results depend on the processing

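TPM over all transcripts, both scalings without abundant genes, named genes only and trend removal were tests chosen after seeing the data; the rest were planned, and the cause of each change was not tested unless stated. Leaving out centring, which cannot move a list against its random lists, lists outside the random range stayed there in 118 results and came inside in 11, and lists inside stayed in 159 and left it in 10. Pparg stayed lower in every alternative run, from -0.89 with a pseudocount of 5 FPKM to -2.76 with trends removed. The filter of 1 FPKM cannot move the 2-fold counts, because the pseudocount bars such calls below it. Without read counts, the depth behind low genes is unknown.

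Against 4510 loci higher and 505 lower, a pseudocount of 5 FPKM gave 2163 and 224, upper-quartile scaling 1202 and 1306, centring 1107 and 1268, TPM over all transcripts 602 and 1030, scaling without the 100 most abundant genes 2721 and 1060, the version of it that keeps the pseudocount in the deposited unit 1969 and 893, and trend removal (named genes) 633 and 927. A 1.5-fold limit gave 7071 and 778, and a 4-fold limit 857 and 182, by construction. At least 5 FPKM left 288 lower. The median log2 fold was 0.07 with upper-quartile scaling and 0.003 with TPM over all transcripts.

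List values here are medians less the random median. Fatty acid oxidation without a filter was -0.43. Extracellular matrix was -0.21 with a pseudocount of 5 FPKM, -0.087 at 5 FPKM or more, -0.35 with all lengths and -0.16 with trends removed. TGFb and BMP response without a filter was 0.27. The unfolded protein list was 0.31 with a pseudocount of 5 FPKM, 0.33 without a filter and 0.41 with trends removed. Immediate early genes were 0.80 with a pseudocount of 0.1 FPKM and 0.52 with trends removed. Each of these then lay inside the random range. The mTOR and IGF list passed above it with a pseudocount of 0.1 FPKM (0.64), TPM (0.59), upper quartile (0.56), the most abundant transcript (1.02), TPM over all transcripts (0.42), both scalings without abundant genes (0.64 and 0.56) and trends removed (0.53). Reference genes without a filter fell below it (-0.51). The Wnt and adipocyte lists without a filter stayed below it, but nearer to their random medians (-0.37 against -2.51, and -0.25 against -0.99). The p53 list, inside the range as reported, passed above it (1.67) at 5 FPKM or more, where fewer members are left and Cdkn1a, Mdm2, Ccng1 and Perp enter through the deficient library alone. Of the single-gene results under alternatives, 897 were counted as the same, 672 as moved and 4 as reversed. The 4 were Cpt2 (-0.0008), H2-D1 (-0.27) and Cd14 (-0.10) with trends removed, and Acta2 (-0.058) with TPM over all transcripts. Genes with smaller folds also changed sign by centring, such as Acaa2 (0.77 as deposited, -0.09 centred) and Hadha (0.63 and -0.23).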

Other observations

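The highest genes included the retinoid genes Crabp1, which rose from 2.16 to 244 FPKM, and Aldh1a1, which rose from 0.34 to 38.6 FPKM. No retinoid list had been fixed, so these are values chosen after they were seen, and no theme was tested.

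Within the interferon list 3 kept members were listed at 0 in the deficient library: Irf7 (2.10 FPKM in the floxed library), Oas1a (8.74 FPKM) and Oasl2 (58.0 FPKM). Ifit2 differed from its relative Ifit1, at 12.3 FPKM in the floxed and 11.03 FPKM in the deficient library. Bone matrix genes Ibsp (7.56 FPKM) and Mmp13 (5.54 FPKM), a collagenase gene, were present in the floxed library and listed at 0 in the deficient library. Perp, a p53 target gene, was listed at 0 in the floxed library and at 6.24 FPKM in the deficient library. These genes were named after their values were seen.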
